A study of Mus musculus with 4 samples.

How the data were processed

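Hepatocyte RNA from 4 mice was compared on 4 two-colour Agilent arrays. Per the labels' protocols, livers were perfused with collagenase, the homogenized tissue was washed by centrifugation, and total RNA was taken from the pelleted cells. The protocols name no sort for hepatocytes, so that other liver cells in a pellet would add to its RNA. Per the labels, HepKO mice carried floxed Pnpt1 alleles and 1 copy of Albumin-Cre, which acts in hepatocytes, and WT mice carried the floxed alleles without Cre. Per the labels, 1 HepKO male was paired with 1 WT male, and 1 HepKO female with 1 WT female, each matched for age and litter. Each pair was hybridised on 2 arrays with the dyes exchanged. In replicate 1 of a pair the HepKO RNA was in Cy5, and in replicate 2 it was in Cy3. The 2 arrays of a pair shared the same RNA extracts and were counted as 1 replicate, so n = 2 pairs throughout. Both arrays of a pair lay on 1 slide, so that sex, age and slide cannot be told apart between the pairs. Samples were grouped by their labels alone. The labelled sex was checked afterwards against Xist and Y-linked genes, and no sample was moved. Xist, Ddx3y, Eif2s3y and Kdm5d ran against the labelled sex in both pairs, while the Y-linked gene Zfy2 did not separate the pairs.

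Per the file headers, the scanner images were read with Agilent Feature Extraction 10.2.1.3, and the deposited spot intensity values used here are the mean pixel intensity of each spot and the median intensity of its local background, in the green and the red channel, with nothing subtracted. The deposited log10 ratio of red over green in the same files had been background-subtracted and dye-normalized by that software, per the file headers. The authors' value table of the series holds the same log10 ratios to rounding: its columns correlated at 1 or -1 with the log ratio of their own array over 43379 spots, with the sign turned on the arrays with HepKO in Cy3. Its direction is therefore HepKO over WT in every column, and the median of each column was 0. Both log10 sources served as alternatives. Further processing by the authors is not given in the sources used here.

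Each array's signal was corrected for background with the normexp model (offset 50) and normalized by loess within the array in limma 3.58.1 under R 4.3.3. Control spots (1639 of 45018) had weight 0 in the loess fit. Spots with a non-uniformity or population outlier flag, for the spot or its background, were left out (178 to 260 spots per array), and no spot was saturated. These flagged spots were also left out before the normexp parameters were estimated. The rule that flagged spots are left out was fixed before the data were examined, but the point at which they leave was settled afterwards, when the fit on all spots had been seen. On female pair replicate 2 the local background reached 41156 in the green channel, against a median of 29, and 39 spots carried a background flag. With those spots in the fit the SD of that array's log2 ratios was 0.414 instead of 0.691, and 0 genes passed the test used here in place of 1808. The fit on all spots is therefore given beside the counts it changes.

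Log2 ratios were turned to HepKO over WT on every array, spots of 1 probe were averaged, and the 2 dye orientations were averaged to 1 value per pair, in which a dye effect cancels. A probe was kept if it was well above background on both arrays of at least 1 pair in the channel of at least 1 genotype, which left 22844 of 41174 probes. The scanner files used here hold no gene symbols. Probes were named by matching the RefSeq accession of each probe, without its version, to an annotation table of assembly GRCm38.p6, which was used for names alone. This named 22951 probes (55.7%) from 16358 genes, left 18223 probes without a name, and gave no probe several names. The brightest kept probe stood for a gene. No positions are given, because the probe annotation in the file headers refers to an older build.

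The test was the limma linear model with an intercept on the 2 pair values, with moderated variances (eBayes) and Benjamini-Hochberg adjustment over the 11495 named genes measured. With 2 pairs there is 1 residual degree of freedom, and the moderated test borrowed 3.12 more from the other genes. The threshold was an adjusted p of 0.05. Gene lists were tested with camera at a preset correlation of 0.01 and adjusted over the 33 lists with at least 5 measured genes. Camera with an estimated correlation and fry were run beside it. Differences between the male and female pair were not tested, because each pair is 1 replicate.

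Groups, tests, alternatives, 34 gene lists and the rule for named genes were fixed before the data were examined. Named genes were Pnpt1, the 10 largest log2 changes in each direction past the threshold with the same sign on all 4 arrays, and the 2 to 4 members with the largest absolute change in each described list. RIKEN, Gm, LOC and accession-type names were counted but passed over. Some list members that this rule would name are not reported here. A gene not well above background in 1 genotype on any array has only a bound, given for the pair in which the other genotype was, and Hao2 has one in the female pair on the same terms. It is the mean signal in the brighter genotype over the mean, per array, of the higher of the dim probe's own signal and the lowest signal called well above background, after loess and Aquantile normalization. The lists covered mitochondrial, interferon, stress, metabolic, secretory, cell cycle, fetal, sex-biased, clock, matrix and cell type marker genes.

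The fits were tested on simulated log2 ratios for the same 11495 genes with 200 changed genes. Over 12 simulated sets, 3.36% of genes changed by 1 on the log2 scale were called, 86.6% of those changed by 2, and 99% of those changed by 4, and 5.81% of all calls were unchanged genes. With 4000 changed genes, 89.9% of genes changed by 1 were called. The simulated variances were drawn from the prior that the moderated test had fitted to these data. The share of unchanged genes among the calls therefore does not test whether that prior holds. In a simulated list test, 1% of 1000 random lists of 25 unchanged genes had an unadjusted camera p below the 0.05 threshold. The simulated genes varied independently of one another, so this does not test camera on lists whose genes move together. The estimated correlation was 0.72 in the interferon-stimulated list, for example. The number of arrays limits the precision of every value here. The alternatives covered the background correction, both normalizations, the filter on dim probes, the choice of probe, the replicate unit, the variance prior, each dye orientation and each array or pair left out.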

Results

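Gene expression in hepatocytes of mice with a liver-specific knockout (HepKO) of Pnpt1, which encodes PNPase, an RNA exonuclease found mainly in mitochondria, was compared with that in wild-type (WT) hepatocytes. 4 two-colour arrays measured 2 sex-, age- and litter-matched pairs of C57BL/6J mice. They were a pair labelled male, aged 12.29 weeks, and a pair labelled female, aged 4.29 weeks. The labels give 2 different ages for the male pair, and that of its characteristics is used here. Per the labels, the male HepKO mouse weighed 17.37 g with a liver of 1.19 g, and its WT partner weighed 22.7 g with a liver of 1.62 g. The female HepKO mouse weighed 16.81 g with a liver of 0.89 g, against 18.49 g and 0.97 g in its partner. Of the sex-chromosome genes measured, all but Zfy2 ran against the labelled sex in both pairs. In HepKO and in WT alike, the Y-linked genes Ddx3y, Eif2s3y and Kdm5d were well above background on 2 of 2 arrays of the pair labelled female and on 0 of 2 of the pair labelled male. Xist, which is transcribed from the inactive X chromosome of females, was above background on 2 of 2 arrays of the pair labelled male and on 0 of 2 of the pair labelled female. The Y-linked gene Zfy2 did not separate the pairs. It was above background in HepKO on 2 of 2 arrays and in WT on 1 of 2 arrays of each pair. Xist, Ddx3y, Eif2s3y and Kdm5d argue, in both genotypes, that the pair labelled male was female and the pair labelled female was male. The pairs keep the names of their labels below, and the age and weights that go with their arrays are open. The HepKO over WT ratio is taken within a pair and does not use these labels. Between 48.2% and 58.6% of the 41174 probes were well above background, depending on the array and channel. Values below are log2 HepKO over WT as the mean of 2 pairs ± the moderated SE from limma (n = 2 pairs), and adjusted p-values come from the same model.

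Pnpt1 itself was measured by 2 probes. The brighter one, A_51_P453343, had a log2 ratio of -0.10 ± 0.20 (adjusted p = 0.747), with 0.31 and 0.058 on the arrays of the male pair and -0.38 and -0.38 on those of the female pair. The dimmer one, A_52_P229271, was below 0 on all 4 arrays, with -0.67 and -0.32 in the male pair and -0.50 and -0.60 in the female pair. Its mean was -0.52 ± 0.13, with an adjusted p of 0.0799 over 22807 probes. Neither probe passed the threshold. Which part of the gene was deleted, and where the probes lie relative to it, is not given in the sources used here, and a probe outside the deleted part would not check the genotype.

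HepKO hepatocyte preparations differed from WT in 1808 of 11495 genes (15.7%), of which 1379 were higher and 429 lower. The 10 largest increases were led by Rsad2 (viperin, an antiviral enzyme; 6.71 ± 0.42, adjusted p = 0.0115) and Cxcl10, an interferon-induced chemokine (5.96 ± 0.65). They also held Phf11d (5.87 ± 0.37), the interferon-induced GTPase Tgtp1 (5.75 ± 0.36), Spats2l (5.74 ± 0.16), D17H6S56E-5 (5.56 ± 0.15) and the interferon-induced Ifit1 (5.29 ± 0.36). The stress-induced nuclear protein Nupr1 (5.42 ± 0.26), alpha-fetoprotein (Afp; 5.39 ± 0.56), a product of fetal hepatocytes, and Ly6d (5.23 ± 0.15) completed them. The 10 largest decreases included 4 genes for major urinary proteins, Mup1 (-5.09 ± 0.47), Mup5 (-4.39 ± 0.43), Mup3 (-4.13 ± 0.14) and Mup4 (-3.44 ± 0.20), which are near-identical paralogs that a probe may not tell apart. The lysophosphatidylcholine transporter Mfsd2a (-4.41 ± 0.31) and the succinate receptor Sucnr1 (-3.88 ± 0.48) were also among them. The organic anion transporter Slco1a1 (-3.81 ± 0.31), the glutamate transporter Slc1a2 (-3.55 ± 0.34), Ugt3a1 (-3.46 ± 0.38) and the sulfotransferase Sult2a8 (-3.35 ± 0.41) were the others.

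**Figure D1:**
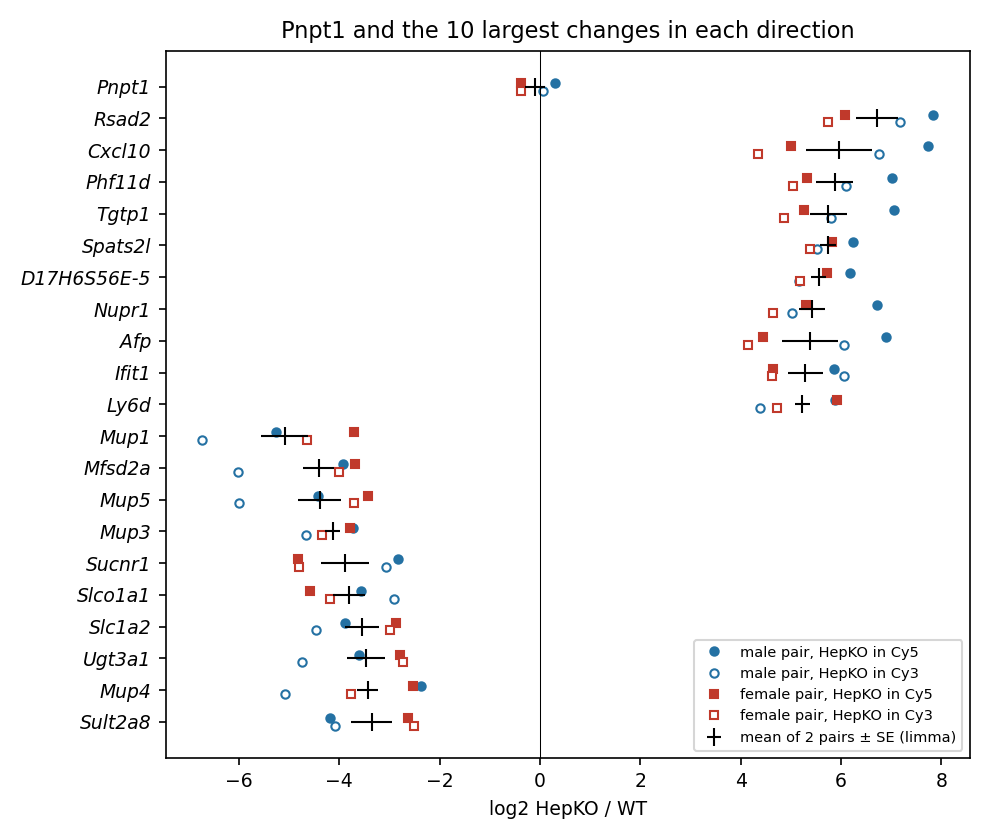
Log2 HepKO over WT (horizontal axis) of Pnpt1 and of the 10 genes with the largest change in each direction; circles and squares are single arrays of the male and female pair, filled where HepKO was in Cy5, and black bars are the mean of 2 pairs ± SE from limma. All 4 arrays lie on the same side of 0 for every gene but Pnpt1, as the rule that chose these genes required.

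All 1808 genes had the same sign on all 4 arrays, and 1039 of the higher and 263 of the lower genes changed at least 2-fold. The test could not call a gene whose 2 pair values differ in sign. The agreement of the pairs is therefore no separate support for these genes. The adjusted p-values lay close to the threshold: the smallest was 0.00986, while 4179 genes had an unadjusted p below the same threshold. The counts ended in 2 settings. Without the filter on dim probes 0 genes passed in limma (smallest adjusted p 0.0677, 4647 genes at an unadjusted p below the threshold), and with normexp fitted on all spots, a setting added after seeing the data, 0 passed (smallest adjusted p 0.0707, 3021 genes unadjusted). Without male pair replicate 2 the counts were 921 higher and 204 lower. The median over all genes was 0.083, and 0.18 with median centring of each array. Among 587 changed genes with more than 1 probe, 16 had probes of opposite sign, and the probes of Tgtp1 ranged from 3.22 to 5.75 and those of Spats2l from 2.39 to 5.74. At the level of probes, 274 probes without a gene name were higher and 221 lower among 6385 tested.

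Interferon-stimulated genes, which cells switch on in response to type I or II interferon, were higher as a group. Of 41 measured, 39 rose and none fell, and 40 rose and 1 fell when adjusted over the list alone. The list median was 2.83, with 3.61 in the male and 2.34 in the female pair (camera adjusted p = 1.04e-18, or 0.651 with an estimated correlation). Besides Rsad2, Cxcl10 and Ifit1, the 2'-5' oligoadenylate synthetase-like gene Oasl2 rose by 5.22 ± 0.19. On the same arrays the macrophage marker list had a median of 2.08 and the lymphocyte list 1.08. With the Feature Extraction log ratios the lymphocyte median was 2.89, against 3.03 for the interferon-stimulated genes.

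Cell cycle genes were the other list in which nearly every member changed. Of 44 measured, 42 rose and none fell (43 rose when adjusted over the list alone), with a median of 2.07, 1.99 in the male and 2.30 in the female pair (camera adjusted p = 1.02e-20, or 0.651 with an estimated correlation). The mitotic genes Cdc20 (5.05 ± 0.22), Kif20a (4.28 ± 0.20), Ccna2 (4.03 ± 0.21) and Birc5 (3.82 ± 0.22) had the largest changes. Of 19 p53 targets and apoptosis genes, 8 rose and none fell, or 16 rose and 2 fell when adjusted over the list alone, with a median of 0.90 (camera adjusted p = 0.000381, or 0.655 with an estimated correlation). They were led by Phlda3 (3.15 ± 0.16) and by Cdkn1a (2.83 ± 0.16), the cell cycle inhibitor p21. The fetal liver list was led by Afp and Ly6d. In it 6 of 12 genes rose and none fell, with the same counts when adjusted over the list alone, and the median was 1.25 (camera adjusted p = 0.00127, or 0.651 with an estimated correlation). On the same arrays the macrophage marker list had a median of 2.08 and the endothelial list 1.13.

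Markers of every non-hepatocyte liver cell type on the lists, erythroid cells apart, had medians above 0 that passed camera at the preset correlation. With an estimated correlation none passed, with an adjusted p of 0.721 for neutrophil markers, 0.898 for erythroid markers and 0.651 for each of the other lists of this group. Macrophage markers had a median of 2.08, and 21 of 25 rose and none fell, or 22 rose and 1 fell when adjusted over the list alone (camera adjusted p = 1.2e-08). The monocyte chemokine Ccl2 (5.09 ± 0.63) and the scavenger receptor Marco (4.26 ± 0.29) led them. Endothelial markers had a median of 1.13 with 13 of 20 higher, or 15 when adjusted over the list alone (camera adjusted p = 2.43e-06), led by Cd34 (2.61 ± 0.19) and Lyve1 (2.07 ± 0.16). Lymphocyte markers had a median of 1.08 with 13 of 21 higher, or 15 when adjusted over the list alone (camera adjusted p = 2.38e-06), led by the chemokine Ccl5 (5.08 ± 0.33) and the granzyme Gzmb (2.83 ± 0.35). Cholangiocyte and progenitor markers had a median of 1.00 with 4 of 12 higher, or 6 when adjusted over the list alone (camera adjusted p = 0.000485), led by osteopontin (Spp1; 3.96 ± 0.40) and Bicc1 (3.39 ± 0.17). Stellate cell and fibroblast markers had a median of 0.73 with 4 of 15 higher, or 9 when adjusted over the list alone (camera adjusted p = 0.00321). Hand2 (0.99 ± 0.18, adjusted p = 0.0396) led those and lost its call without male pair replicate 2 (0.059) or without female pair replicate 1 (0.0501). Neutrophil markers had a median of 0.77, 1.24 in the male and 0.35 in the female pair, with 3 of 13 higher by either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 0.00404), led by S100a9 (3.21 ± 0.18). The erythroid list (8 genes, median 0.45, camera adjusted p = 0.826) did not pass, with 1 gene higher and 1 lower, or 1 and 2 when adjusted over the list alone. In it, the globin gene Hba-a1 rose by 3.27 ± 0.16 and Alas2, an enzyme of heme synthesis, was lower at -0.90 ± 0.14, with an adjusted p of 0.0514 without male pair replicate 2. Extracellular matrix genes, with a median of 1.04, had 21 of 33 members higher and none lower (23 when adjusted over the list alone; camera adjusted p = 1.54e-07), with the galectins Lgals3 (3.59 ± 0.41) and Lgals1 (3.28 ± 0.28) behind Spp1. Several medians were over 1.5 times larger with the Feature Extraction log ratios, which gave 2.89 for lymphocyte, 2.73 for cholangiocyte and 2.64 for neutrophil markers, 3.55 for cell cycle, 3.49 for fetal liver, 1.79 for matrix, 1.42 for immediate early and 0.89 for NRF2 genes. The macrophage median was 2.38 there, below the first 3 of these. With probes well above background throughout, the medians were 2.20 for lymphocyte and 2.16 for cholangiocyte markers, 3.36 for fetal liver and 0.80 for NRF2 genes. Without the filter on dim probes the cholangiocyte median was 0.44.

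**Figure D2:**
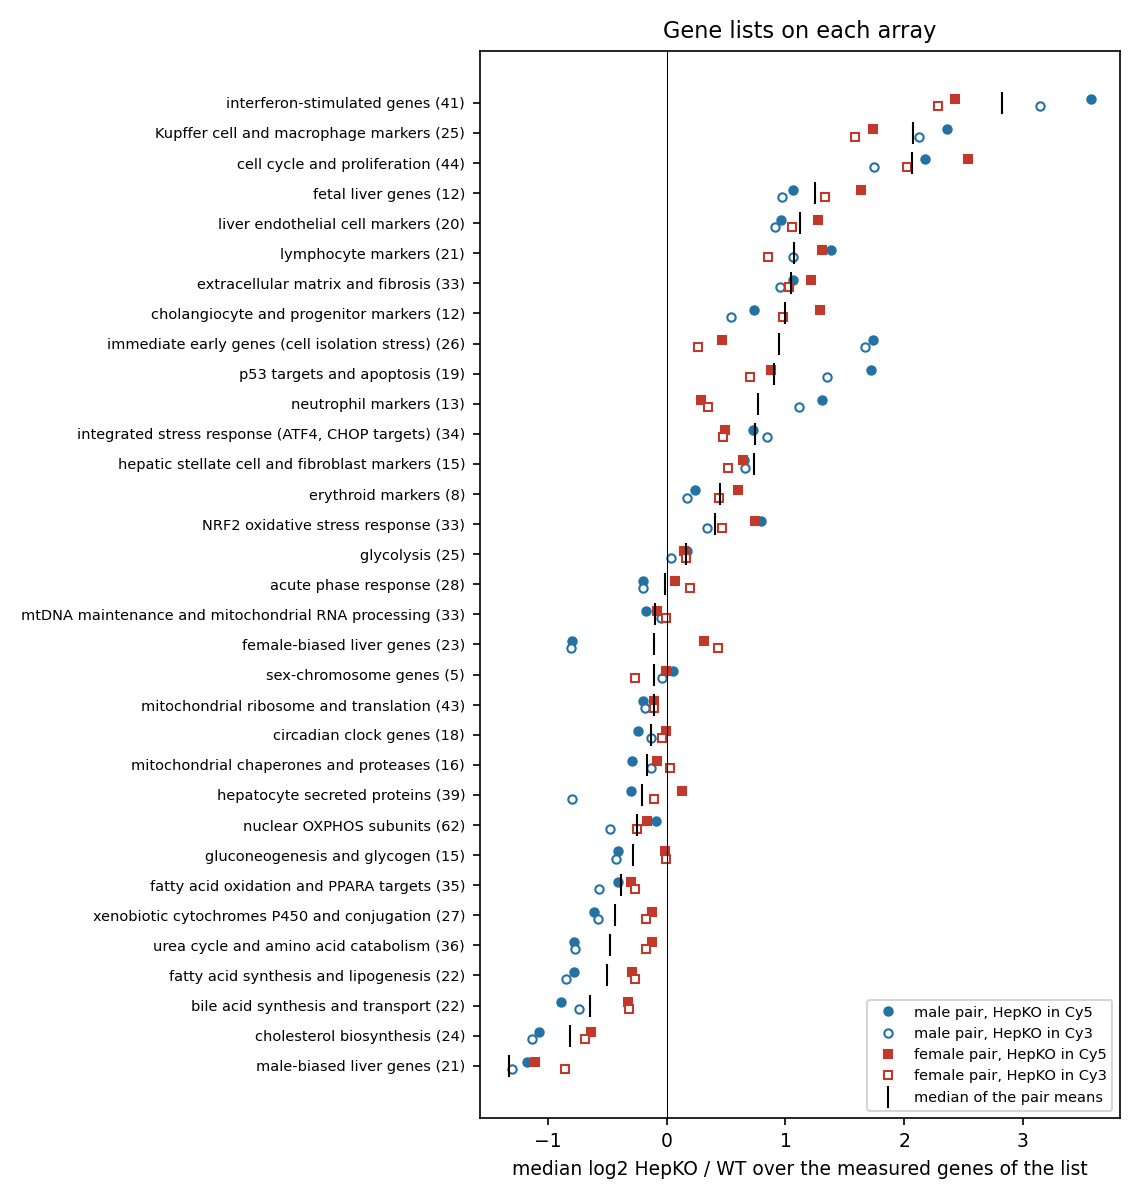
Median log2 HepKO over WT (horizontal axis) of each of the 33 gene lists tested, with the number of measured genes in brackets; symbols are single arrays, filled where HepKO was in Cy5, and the black tick is the median over genes of the mean of both pairs. Interferon-stimulated genes lie at 2.83 and male-biased liver genes at -1.33.

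Stress responses rose in part. On the same arrays the macrophage marker list had a median of 2.08 and the endothelial list 1.13. Of 34 integrated stress response genes, which ATF4 and CHOP induce when protein synthesis or amino acid supply is disturbed, 8 rose and none fell, or 15 when adjusted over the list alone (median 0.74, camera adjusted p = 0.0012, or 0.663 with an estimated correlation). Nupr1 and the transcription factor Atf3 (3.86 ± 0.44) led them. Of 33 NRF2 targets, which answer oxidative stress, 12 rose and none fell, or 12 rose and 1 fell when adjusted over the list alone (median 0.40, camera adjusted p = 0.00081, or 0.651 with an estimated correlation). The glutathione transferases Gsta1 (3.34 ± 0.38) and Gsta2 (2.63 ± 0.31) and the carbonyl reductase Cbr3 (2.78 ± 0.15) had the largest changes. This list lost its call with median centring of each array (adjusted p = 0.0711), and its median was 0.67 on the arrays with HepKO in Cy5 alone. Immediate early genes, which also answer the isolation of cells from tissue, had 7 of 26 members higher and none lower, or 13 when adjusted over the list alone, and a median of 0.94 (camera adjusted p = 0.00081, or 0.721 with an estimated correlation). Their median was 1.71 in the male and 0.37 in the female pair. Besides Atf3, Klf4 rose by 2.57 ± 0.32. The acute phase list did not pass (camera adjusted p = 0.514), except as lower with median centring (median -0.29, adjusted p = 0.0178). Its median was -0.013 and its mean 0.17, with opposite signs, and 5 of 28 genes were higher and 2 lower, or 6 and 4 when adjusted over the list alone. In it, Tnfrsf12a (2.98 ± 0.51) lost its call without male pair replicate 2 (adjusted p = 0.0529), and the endotoxin receptor Cd14 rose by 2.69 ± 0.43. The next largest values were below 0, with Hamp2 lower at -1.99 ± 0.29 and Orm3 at -2.00 ± 0.46 (adjusted p = 0.0614), which did not pass.

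Nuclear genes for mitochondrial proteins changed little by comparison. The 62 nuclear-encoded subunits of oxidative phosphorylation had a median of -0.25 (camera adjusted p = 3.38e-06, or 0.651 with an estimated correlation), but 1 of them passed alone, Cox6c (-0.83 ± 0.15, adjusted p = 0.0384), and none when adjusted over the list alone. Cox6c lost its call without male pair replicate 2 (0.0773), without female pair replicate 1 (0.052), with the Feature Extraction log ratios (0.0723), with the authors' value table (0.0731) and on the arrays with HepKO in Cy5 alone (0.0573). The subunits' median was -0.13 without male pair replicate 2, -0.11 on the arrays with HepKO in Cy5 alone and -0.47 with median centring of each array. The 43 genes for mitochondrial ribosome and translation factors had a median of -0.11 (camera adjusted p = 0.00168, or 0.651 with an estimated correlation), with 1 lower, Mrpl34 (-1.28 ± 0.17), and none when adjusted over the list alone. Of 33 genes for mtDNA maintenance and mitochondrial RNA processing, 2 were lower and none when adjusted over the list alone (median -0.10, camera adjusted p = 0.0394, or 0.651 with an estimated correlation). The mitochondrial transcription factor Tfb2m was one of them (-1.02 ± 0.17, adjusted p = 0.0327, 0.0509 without male pair replicate 2 and 0.0532 with median centring). This list's call was lost with median centring of each array (median 0.033, adjusted p = 0.0795), with the strict filter on dim probes (0.0892) and on the arrays with HepKO in Cy3 alone (0.0537), and its median was -0.034 without male pair replicate 1. With the Feature Extraction log ratios or the authors' value table the median was -0.20 for this list and -0.21 for the mitochondrial ribosome list. Mitochondrial chaperones and proteases did not pass (16 genes, none changed by either adjustment, over all genes or adjusted over the list alone; median -0.16, mean -0.015, camera adjusted p = 0.284), with Lonp1 at 0.55 ± 0.18 and Hspa9 at 0.45 ± 0.14. With median centring they passed as lower (median -0.10, adjusted p = 0.0353). No probe was named for a gene encoded by mtDNA, so those transcripts were not analysed here. The hepatocyte secreted protein list, on the same arrays, had a median of -0.21.

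Lipid metabolism lists had medians below 0. On the same arrays macrophage markers had a median of 2.08, endothelial markers 1.13 and hepatocyte secreted proteins -0.21. Of 24 cholesterol biosynthesis genes, 9 were lower and none higher, or 19 lower when adjusted over the list alone, with a median of -0.81, -1.01 in the male and -0.59 in the female pair (camera adjusted p = 4.2e-10, or 0.651 with an estimated correlation). Stard4 (-1.57 ± 0.20) and mevalonate diphosphate decarboxylase (Mvd; -1.51 ± 0.25) led them. Of 35 genes of fatty acid oxidation and PPARA targets, 7 were lower and 1 higher by either adjustment, over all genes or adjusted over the list alone (median -0.38, camera adjusted p = 1.26e-05, or 0.651 with an estimated correlation). The uncoupling protein Ucp2 rose by 2.07 ± 0.21. Of 22 lipogenesis genes, 5 were lower and 3 higher, or 7 and 3 when adjusted over the list alone (median -0.50, camera adjusted p = 0.00103, or 0.651 with an estimated correlation), with -0.82 in the male and -0.24 in the female pair. The fatty acid transporter Cd36 rose by 3.27 ± 0.33, while the desaturases Fads1 (-2.23 ± 0.21) and Scd1 (-1.99 ± 0.15) were lower. Of 22 bile acid genes, 5 were lower and 2 higher, or 9 and 2 when adjusted over the list alone (median -0.64, camera adjusted p = 0.00564, or 0.651 with an estimated correlation). After Slco1a1 the largest change was in the oxysterol hydroxylase Cyp7b1 (-2.46 ± 0.20). With median centring of each array the fatty acid oxidation median was -0.62.

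Other hepatocyte functions were lower in part. Macrophage markers had a median of 2.08 and endothelial markers 1.13 on the same arrays. Of 27 xenobiotic cytochromes P450 and conjugation genes, 7 were lower and 3 higher, or 11 and 4 when adjusted over the list alone. Their median was -0.44, -0.58 in the male and -0.15 in the female pair (camera adjusted p = 0.0109, or 0.702 with an estimated correlation). Cyp2c55 rose by 4.25 ± 0.24, while Cyp2c54 was at -3.20 ± 0.53 (adjusted p = 0.0331), with 0.0512 without male pair replicate 2 and 0.0521 without female pair replicate 1. This list's call was lost with the Feature Extraction log ratios (0.0568), with the authors' value table (0.0579) and with a trended robust prior (0.0604). Urea cycle and amino acid genes had a median of -0.48, -0.87 in the male and -0.17 in the female pair (camera adjusted p = 4.89e-06, or 0.702 with an estimated correlation). Of 36, 3 were lower and 1 higher, or 1 and 0 when adjusted over the list alone. Ahcy, which hydrolyses S-adenosylhomocysteine, fell by 1.62 ± 0.17. Hepatocyte secreted proteins had a median of -0.21, -0.60 in the male and -0.055 in the female pair (camera adjusted p = 0.00128, or 0.721 with an estimated correlation), with 3 of 39 lower and none higher, or 1 when adjusted over the list alone. Apoa2 fell by 1.42 ± 0.15. The secreted protein median was 0.0068 on the arrays with HepKO in Cy5 alone and -0.72 with median centring, and it was -0.37 without male pair replicate 1, -0.10 without male pair replicate 2 and -0.11 without female pair replicate 2. Gluconeogenesis and glycogen genes had a median of -0.28, with -0.45 in the male and -0.046 in the female pair, and none of 15 changed by either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 0.0201, or 0.721 with an estimated correlation). The list lost its call with the Feature Extraction log ratios (0.086) and with the authors' value table (0.0857). The glycolysis list did not pass (median 0.16, camera adjusted p = 0.776), with 7 of 25 genes higher and 1 lower, or 8 and 6 when adjusted over the list alone. Its median was -0.051 with median centring, which gave -0.76 for xenobiotic, -0.80 for urea cycle and -0.44 for gluconeogenesis genes. In the glycolysis list the kinase Pdk1 fell by 2.23 ± 0.23 and the phosphofructokinase Pfkp rose by 1.85 ± 0.16.

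Genes known to be higher in male than in female mouse liver were lower in HepKO as a group. Of 21 measured, 8 were lower and none higher, or 12 lower and 1 higher when adjusted over the list alone, with a median of -1.33, -1.21 in the male and -0.98 in the female pair (camera adjusted p = 2.98e-07, or 0.651 with an estimated correlation). The Mup genes and Slco1a1 had the largest changes. Female-biased genes did not pass (median -0.11, camera adjusted p = 0.0837), except as lower with median centring (median -0.22, adjusted p = 0.00337), and 1 of 23 was lower and none changed when adjusted over the list alone. Their median was -0.77 in the male and 0.42 in the female pair, so that the value near 0 joins opposite directions. Cyp2a4 was at 2.38 ± 0.87 (adjusted p = 0.14). Sult3a1 was not well above background in HepKO on any array, and in WT it was so on the 2 arrays of the male pair (adjusted p = 0.239). In that pair it was at least 22.9-fold lower in HepKO, while in the female pair neither genotype was above background. The circadian clock list did not pass (median -0.13, camera adjusted p = 0.118), with 1 of 18 genes lower, or 5 when adjusted over the list alone. The 2 largest values in it, Tef (-1.16 ± 0.24) and Nr1d1 (-1.09 ± 0.25), did not pass. Of 5 sex-chromosome genes none changed by either adjustment, over all genes or adjusted over the list alone (median -0.11, camera adjusted p = 0.514). These values join 1 pair with signal and 1 pair at background for each of Xist, Ddx3y, Eif2s3y and Kdm5d. In the pair labelled female, where they were above background, Eif2s3y was at -0.19 and Kdm5d at -0.22.

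**Figure D3:**
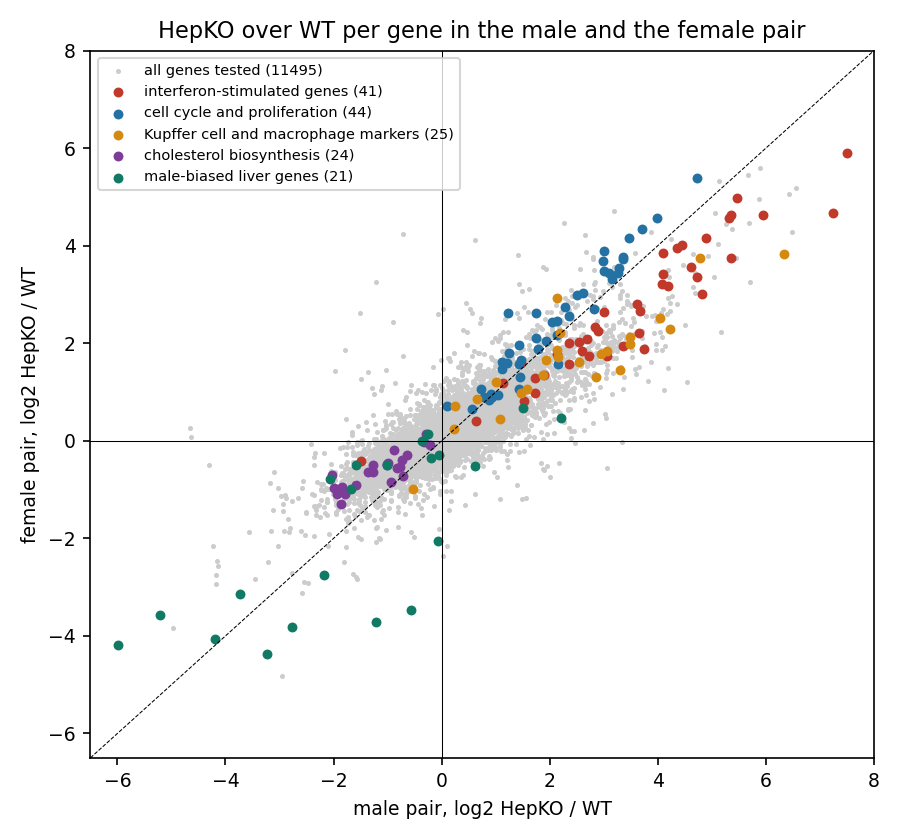
Log2 HepKO over WT of each of the 11495 genes in the male pair (horizontal axis) and the female pair (vertical axis), each the mean of both dye orientations; colours mark 5 gene lists and the dashed line marks equal change. The SD over genes is 0.940 in the male pair and 0.711 in the female pair.

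The male and the female pair were compared as values, since each pair is 1 replicate and the difference has no test. Across genes, which are not independent replicates, the 2 pairs correlated with Pearson's r = 0.839 and Spearman's rho = 0.797. The arrays within a pair correlated at 0.932 in the male and 0.944 in the female pair. The least-squares slope of female on male values was 0.635, which the imperfect correlation also lowers. The SD over genes was 0.940 in the male and 0.711 in the female pair. Changes were larger in the male pair for 1315 of the 1808 changed genes (72.7%). Interferon-stimulated genes followed this difference, whereas cell cycle genes had the higher median in the female pair. The signs of both arrays of the male pair were opposite to those of both arrays of the female pair in 972 genes (8.46%). In 13 of these the change was at least 2-fold each way, 3 higher and 10 lower in the HepKO mouse of the male pair, among them the peroxisomal oxidase gene Hao2 (-1.22 in the male pair, and at least 9.62-fold higher in HepKO in the female pair, where WT was not above background), named after its values were seen. The labelled sex, the age and the slide differ together between the pairs, and Xist, Ddx3y, Eif2s3y and Kdm5d run against the labelled sex in both.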

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

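Both arrays of the male pair and both arrays of the female pair moved in opposite directions for 16 genes reported here and for 2 gene lists. The differences below are log2 HepKO over WT in the male pair minus that in the female pair. None was tested, because each pair is 1 replicate, and labelled sex, age and slide differ together between the pairs. The pairs are named as labelled, while Xist was above background only in the pair labelled male, and Ddx3y, Eif2s3y and Kdm5d only in the pair labelled female.

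By its brighter probe Pnpt1 differed by 0.57 (0.18 in the male and -0.38 in the female pair). Its other probe did not show this, with -0.49 in the male and -0.55 in the female pair. Slc22a26 differed by -4.92 (-4.66 and 0.27), and the Y-linked gene Ddx3y by 0.50 (0.14 and -0.36). Ddx3y was not above background on either array of the male pair, so that its direction there is that of background signal. Among genes that changed at least 2-fold each way, 3 were higher in HepKO in the male pair and lower in the female pair. These were Cyfip2 (difference 2.72), Gadd45g (2.68) and the acute phase gene Saa3 (2.26). The other 10 were lower in HepKO in the male pair and higher in the female pair. They were Isoc1 (-2.15), B3galt1 (-2.22), Nt5e (-2.36), Nnmt (-2.49), Tomm22 (-2.75), Nrep (-2.78), Tmie (-3.40), Mal2 (-3.65), Ugt1a9 (-4.13) and Hao2. The value of Hao2, -4.48, rests on a WT signal that was not above background in the female pair, where HepKO was at least 9.62-fold higher. The 13 genes of these groups were chosen after their values were seen.

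The median of the acute phase list differed by -0.26 (-0.094 in the male and 0.16 in the female pair). That of the female-biased liver genes differed by -1.18 (-0.77 and 0.42).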

How the results depend on the processing

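The 1379 higher and 429 lower genes had the same sign in every alternative in which they were measured, except 1 of the higher genes in the mean over all probes. The alternatives use the same arrays, and the test calls only genes whose pairs agree in sign. This agreement was therefore largely fixed in advance. The fit of normexp on all spots was chosen after seeing the data, and the other alternatives before. Without the filter on dim probes, 0 genes were higher and 0 lower in limma (smallest adjusted p 0.0677, 4647 at an unadjusted p below the threshold). With normexp fitted on all spots, 0 and 0 passed (smallest adjusted p 0.0707, 3021 unadjusted), and the correlation of the pairs was 0.832. In each of these 2 settings 98 named genes lost their call and the calls of the 33 lists stayed. The dim probes lowered the prior degrees of freedom to 1.65, and the fit on all spots to 2.53, from 3.12.

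With 4 arrays taken as independent, 3104 genes were higher and 1676 lower, a count that treats dye-swapped arrays as replicates. With the pair as a random block 961 were lower, with scale normalization 685, on the arrays with HepKO in Cy3 alone 682, and with a 2-fold minimum 263. Leaving out 1 array gave 204 to 572 lower genes, with 204 and 921 higher without male pair replicate 2. Apart from the minimum and the block, the cause was not tested. Single pairs gave no counts, since they leave no test.

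The correlation of the pairs was 0.833 with the Feature Extraction log ratios, 0.833 with the authors' value table, 0.848 with probes well above background throughout, 0.831 on the arrays with HepKO in Cy5 alone, and 0.822 to 0.831 with 1 array left out. By camera with an estimated correlation 0 lists were higher and 0 lower (smallest adjusted p 0.651), and by fry 0 and 0 (smallest 0.0825). Values that changed sign were those of Eif2s3y (0.055 on the arrays with HepKO in Cy5 alone, and -0.32 to 0.027 with 1 array left out), Zfy2 (-0.039 on those with HepKO in Cy5 alone), the sex-chromosome list (0.027 without female pair replicate 2), the erythroid list (-0.067 with the strict filter), the acute phase list (0.00031 with normexp on all spots), and the glycolysis (-0.051) and circadian (0.029) lists with median centring. None of these passed in either setting. Of lists that passed, hepatocyte secreted proteins turned to 0.0068 on the arrays with HepKO in Cy5 alone (adjusted p = 0.0448, 0.00128 before) and mtDNA maintenance to 0.033 with median centring (0.0795, 0.0394 before). Single pairs were not counted among these, and the cause was not tested. Pnpt1 passed in no alternative. Signal near background limits the values of dim probes.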

Other observations

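Families of genes that share the stem of their symbol were examined outside the fixed lists, a choice made after the data were seen. Of 195 families with at least 8 measured genes, 9 were higher and 4 lower by camera at the preset correlation, and none with an estimated correlation (lowest adjusted p = 0.964). Genes of the mouse major histocompatibility complex, which present antigens, led the higher families: 18 of 21 rose and 1 fell, with a median of 1.66 (adjusted p = 1.52e-05). H2-T22 (2.33 ± 0.15), H2-T24 (2.33 ± 0.30) and H2-T10 (2.26 ± 0.16) had the largest changes, and H2-Ke6, which encodes a dehydrogenase, was lower at -0.88 ± 0.15. Further Ifi genes had a median of 3.04 with 7 of 8 higher (0.000987), and the Ms4a genes, several of which are expressed in leukocytes, a median of 2.54 with 7 of 9 higher (0.00192). On the same arrays the macrophage markers had a median of 2.08 and the lymphocyte markers 1.08, and these cells also express such genes. Symbols with the stem H, most of them histones, had a median of 0.95 with 16 of 39 higher and 1 lower (0.00252), led by H1f2 (2.77 ± 0.32) and H4c4 (2.70 ± 0.40). Those with the stem Cd had a median of 0.82 with 25 of 53 higher and 3 lower (0.000987). The Rgs, Ly, Ptpn and Trim families were the other higher ones. The 4 lower families were olfactory receptors (Olfr; median -0.14, 2 of 40 lower, 0.00463), Rdh genes, several of which encode retinol dehydrogenases (-0.38, 3 of 10 lower, 0.0121), Nat genes (-0.48, 4 of 10 lower, 0.0123) and cytochrome P450 genes outside the fixed lists (-0.37, 4 of 30 lower and 1 higher, 0.0322). Over all genes 429 of 11495 were lower, and the share of lower olfactory receptors was near that.

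The tests of the next 3 paragraphs were all chosen after the results were seen, and their permutations are over genes, which are not independent replicates. Interferon-stimulated genes were higher in HepKO. Were this brought by more macrophages and lymphocytes in the pellets alone, these genes would rise no more than the markers of those cells. Their median lay 1.12 above that of the 46 pooled markers, none of which is on the interferon list (permutation p = 0.00028, two-sided), but 0.55 above it with the Feature Extraction log ratios (3.03 against 2.48, permutation p = 0.192), so that more such cells and an interferon response in the hepatocytes cannot be told apart. Over 5 settings of background and normalization the lowest median was 2.68 and the highest camera adjusted p 2.42e-17, which argues against the scanner processing as the whole cause. Immune cells with a high level of these genes per cell stay open too.

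Markers of other liver cell types were higher in HepKO. A lower share of hepatocytes alone would raise every other type alike, whereas the medians of 5 marker lists ranged over 1.34, from 0.73 to 2.08 (permutation p = 0.015, 93 genes, 4 of them on a further list, 77 well above background in WT on at least 1 array). With probes well above background throughout, which left 65 of these genes, the range was 1.47 and did not pass (permutation p = 0.135). In the other settings of background, normalization and filter the range passed, with a permutation p of 0.0008 to 0.0184. Induced genes among the markers could also set the lists apart, so that a lower share of hepatocytes and a change in single types cannot be told apart. Without 7 immune markers taken as inducible (Ccl2, Ccl5, Fcgr1, Cd74, Ctss, Gzmb and Marco) the pooled median was 1.33, against 1.13 for endothelial markers (permutation p = 0.225). These 7 include the genes that led the macrophage and lymphocyte lists, so that leaving them out lowers the median by itself. No endothelial marker was left out in turn. Whether induced genes account for the lead of the immune markers therefore stays open.

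Male-biased liver genes were lower in HepKO. Their median lay below that of the hepatocyte secreted proteins, by a difference of -1.16 (permutation p = 1e-05, the smallest that 100000 permutations can give). The difference was -0.73 to -1.26 over 7 other settings of background, normalization and filter. The permutation counted the 4 near-identical Mup genes as separate genes, so that this contrast alone cannot decide on a loss of hepatocytes. Without the 4 Mup genes the median was -1.05, which differed from that of all genes outside the list by -1.13 (permutation p = 1e-04, the smallest that 10000 permutations can give). The difference was -0.82 to -1.20 over the same settings, which argues against near-identical Mup probes as the whole cause. The comparator of this test was first the secreted proteins, and it was changed to all genes outside the list after the values were seen. Against the secreted proteins the 17 genes left without Mup genes differed by -0.87 (permutation p = 0.00017), and by -0.36 with median centring (permutation p = 0.114). A loss of hepatocytes therefore stays open. The list median was -1.21 in the pair labelled male, where Xist was above background. It was -0.98 in the pair labelled female, where Ddx3y, Eif2s3y and Kdm5d were above background. A loss of male-biased expression in HepKO hepatocytes may be one explanation, but it was not tested. These sex-chromosome genes argue against the labelled sex of both pairs. Body weight, which differed within each pair per the labels, was not tested either.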
